A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

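Gene expression was measured on 6 Affymetrix arrays made for budding yeast, each hybridised with biotin-labelled cRNA prepared from the total RNA of 1 culture. The cultures were haploid MATa cells of the W303 laboratory background, grown to mid-log phase in rich glucose medium. Per the labels, 3 arrays came from wild type cells and 3 from cells in which NPL3 was replaced by the KanMX marker, and the arrays of a group are biological replicates. Both genotype labels also name a deletion of BAR1 and the same ade2, can1, trp1, his3, leu2 and ura3 alleles.

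The deposited values are log2 expression values, 1 per probe set and array. RMA and limma are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. The range of the values and their nearly equal medians on the 6 arrays, 4.81 to 4.98 over all probe sets, are those of normalized log2 data. They were not normalized again for the main results. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a probe set, so a change shared by most transcripts would not be visible in these values.

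Of 10928 probe sets, 7244 had 1 gene symbol in the platform annotation used here, 1 had several and 3683 had none. The genes of 5498 probe sets matched the yeast reference table (assembly R64), and those of 1746 did not. The array also carries probe sets for another yeast species. The 95th percentile of the 1746 unmatched probe sets, 2.13 on the log2 scale, served as the background level. All 1746 have symbols in lower case, against 0 of the 5498 matched ones, but their organism is not named in the annotation used here and some may be older names of budding yeast genes, so the level is approximate. Where a gene had several probe sets (47 genes), the one with the highest mean over all 6 arrays stood for it, and in 3 of these genes 1 probe set moved more than 1.5-fold and another the other way. This left 5449 genes, of which 46 had a mean at or below the background level. Probe sets marked s or x can match several transcripts. No genome sequence was used here, so no coordinates are given, and the reference table served for names, coding lengths, chromosomes and neighbours.

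Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates), with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05 on the adjusted p. A count with a fold change of at least 1.5 was made from the same fit. All adjusted p-values of single genes are from this fit. The 41 gene lists were tested with camera at its preset correlation of 0.01, which compares the members with the other genes, and adjusted over the lists. Camera with a correlation estimated per list, fry, which asks whether the members move one way on balance, and cameraPR on ranks were run beside it. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

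The design, the lists, the rule for named genes and most alternatives were set before the data were examined. The rule names the genes of the strain labels, the 10 largest rises and 10 largest falls among called genes with a symbol, no overlap between the groups and a brighter group above background, the 2 largest rises and falls among called members of each called list and of 6 lists on RNA processing, ribosomal proteins and DNA damage, and the neighbours of NPL3. Other genes named were chosen after their values were seen: the members of the glucose transport list beyond HXT1 and HXT4, and genes in the closing section. The intron lists came from gene names fixed in advance, because no annotation of introns was used here. Lists by GC content, distance from chromosome ends and position downstream of a snoRNA were not run, since they needed a genome or coordinates. Of the fixed list members, 14 were not tested, TRP1 among them.

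The procedure was tested on simulated data with the number of genes and the spread of these arrays. It called 60.3% of genes given a log2 change of 0.3 and 97.6% of those given a change of 1, and 5.93% of its calls were false. The simulated data gave a change to far fewer genes than were called in the arrays, with noise independent between genes. These shares hold for that setting and need not hold for the arrays. The number of arrays limits the precision: with 3 against 3, a two-sided permutation test of a single value cannot give a p below 0.1. The replicate numbers shared by the groups were not treated as pairs. The alternatives were a replicate block, each array left out in turn, median centring, quantile normalization, filters on dim genes, a trended and robust variance model, array weights, averaged or separate probe sets, stricter thresholds and the other set tests. Fits without chromosome I genes and without s and x probe sets were added after the data were seen.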

Results

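Transcript levels were compared between wild type yeast and cells lacking NPL3, which encodes an RNA-binding protein of the SR and hnRNP type that accompanies mRNA from transcription to export. The 6 arrays, 3 per genotype, covered 5449 genes, with values ranging from 0.55 to 13.48 on the log2 scale. Arrays of a group correlated with Pearson r of 0.996 to 0.998 across genes and arrays of different groups with r of 0.956 to 0.961, where genes are not independent replicates. The SD of the difference between 2 arrays was 0.122 to 0.185 within groups and 0.558 to 0.585 between them.

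The NPL3 transcript (YDR432W, chromosome IV) was at 11.15 ± 0.35 in wild type cells and 3.96 ± 0.14 in the deletion (log2, mean ± SD, n = 3 arrays each). It fell by 7.19 (SE 0.16, limma adjusted p = 1.2e-07). Of its neighbours, GPI17 rose by 0.24 (SE 0.05, adjusted p = 0.0025) and CYM1 differed by 0.14 (SE 0.06, adjusted p = 0.079), which did not pass the test. BAR1, deleted in both strains, was below the background level of 2.13 in both, at 1.10 ± 0.15 and 1.06 ± 0.26. LEU2, an enzyme of leucine synthesis, had the largest rise of all named genes, from 2.85 ± 0.07 to 8.51 ± 0.12 (difference 5.66, SE 0.07, adjusted p = 8.3e-09), although both genotype labels name the same leu2 allele. The other marker genes moved less: HIS3 fell by 0.78, CAN1 fell by 0.42 and URA3 fell by 0.29, while ADE2 rose by 0.26. The groups did not overlap for any of these 4.

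**Figure D1:**
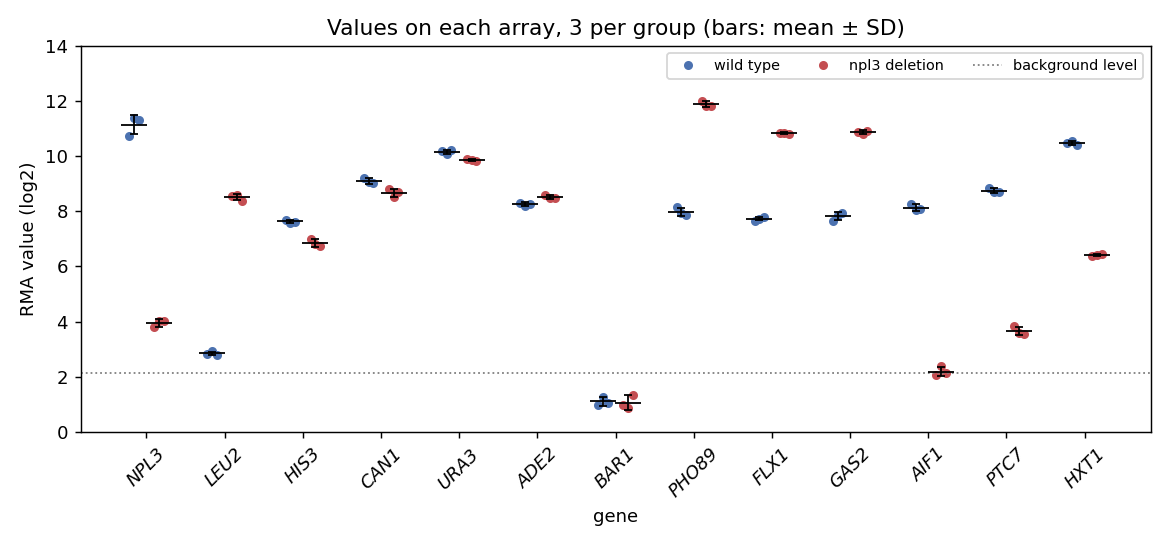
RMA values (log2) of 13 genes on each of the 6 arrays, with wild type in blue and the npl3 deletion in red. Black bars give the mean ± SD of 3 arrays and the dotted line the background level of 2.13. NPL3 fell by 7.19 and LEU2 rose by 5.66, while BAR1 lay below the line in both groups.

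Beside NPL3 itself, the largest falls among genes with a symbol were those of AIF1 (fell by 5.95, SE 0.10), a mitochondrial cell death effector, and PTC7 (fell by 5.10, SE 0.08), a protein phosphatase. AIF1 reached 2.18 ± 0.17 in the deletion, next to the background level. NPL3, absent from the deletion per the labels, still read 3.96 there, so an absent transcript can read above that level. PTC7 (3.66) and HFM1 (3.17) in the deletion, and LEU2 (2.85) and AIM26 (2.34) in wild type, read lower than that. The sizes of these changes are therefore uncertain. YRO2 fell by 4.67, the glucose transporter genes HXT1 and HXT4 fell by 4.06 and fell by 2.97, and the transketolase gene TKL2 fell by 3.21. STP4, HSP30 and the meiotic helicase gene HFM1 followed, at -2.90, -2.82 and -2.68. After LEU2, the largest rises among them were those of PHO89, a sodium-phosphate cotransporter (3.90, SE 0.09), FLX1, a mitochondrial FAD carrier (3.10, SE 0.05), and GAS2, a spore wall glucan-modifying enzyme (3.04, SE 0.08). HES1 of the oxysterol-binding family rose by 2.59, the flocculin gene FLO1 on chromosome I by 2.55, AIM26 by 2.32, the spore protein gene SPO19 by 2.28 and USE1, a SNARE gene, by 2.17. The maltose permease gene MPH2 rose by 2.22 on a probe set that can match several transcripts.

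In total 3369 of 5449 genes (61.8%) changed, 1793 higher and 1576 lower in the deletion, and 2080 were not called. A fold change of at least 1.5 was reached by 923 genes, 451 higher and 472 lower. The groups did not overlap for 3747 genes (68.8%), where chance gives 10% for 3 against 3. The median over all genes was 0.01 on the log2 scale.

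Array controls differed between the genotypes as well. Hybridization controls, bacterial and phage transcripts spiked in before hybridization, averaged 9.31 ± 0.08 in wild type and 8.67 ± 0.60 in the deletion (log2, n = 3 arrays each), and all 9 of their probe sets were lower in the deletion. The difference of the means was -0.63, and -0.29 without npl3 deletion replicate 1 (7.99). Labelling controls averaged 4.10 ± 0.12 and 4.80 ± 0.20, with 12 of 12 probe sets higher in the deletion. Neither set of array means overlapped (exact permutation p = 0.1 for each, two-sided, the smallest that 3 against 3 can give). The 5′ probe set minus the 3′ probe set was higher in the deletion for all 8 control genes examined, by a median of 0.37, and the groups did not overlap for any of them. These differences stand beside every gene group that follows.

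**Figure D2:**
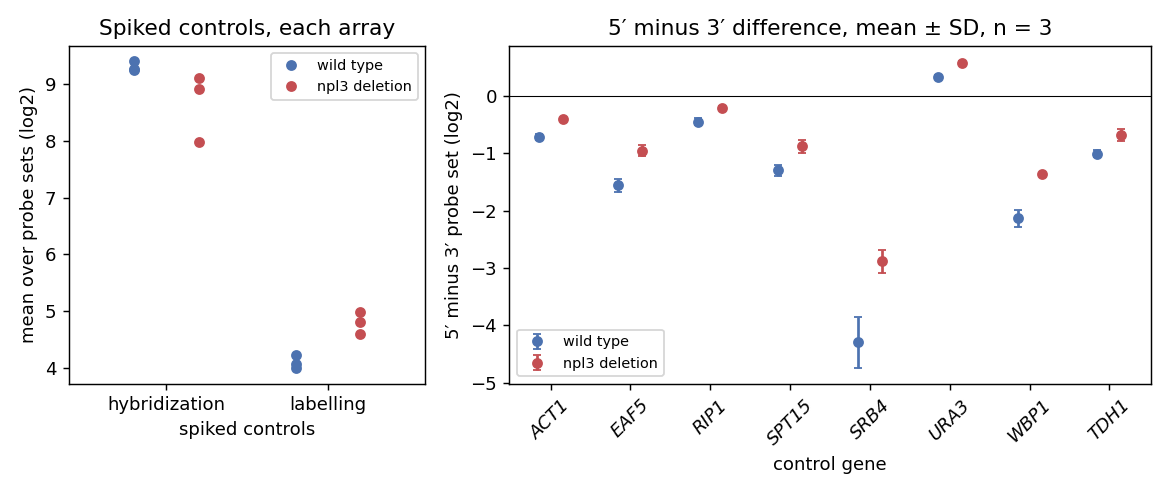
Left, mean log2 value of the spiked hybridization and labelling controls on each array, by genotype. Right, 5′ minus 3′ probe set (log2) of 8 control genes, mean ± SD of 3 arrays, higher in the deletion for 8 of 8.

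The genes of chromosome I stood higher as a block. Of 90 tested, 74 rose and 6 fell, with a median of 0.83 (95% interval over genes 0.687 to 0.907), a fold of 1.77. The medians of the other chromosomes lay between -0.07 and 0.05. The shift was 0.814, 0.821 and 0.807 on the 3 deletion arrays, relative to the wild type mean. Camera over the 16 chromosomes called chromosome I (adjusted p = 1.1e-15), with adjusted p = 0.014 with an estimated correlation. Without chromosome I genes, a fit added after the data were seen, 3287 genes were called. That fit leaves out the genes of the block alone, and would not remove any effect of the block's cause on other genes.

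**Figure D3:**
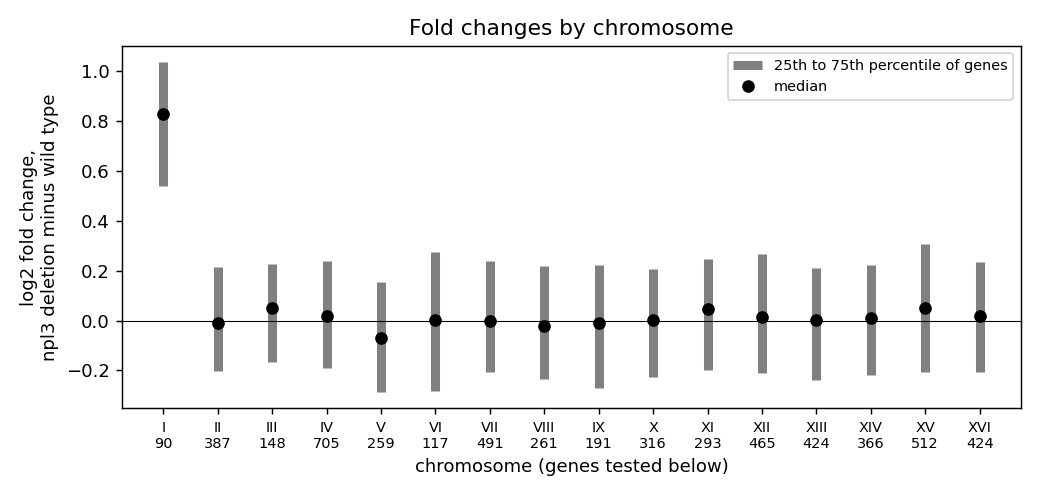
Median (points) and 25th to 75th percentile (bars) of the log2 fold change, npl3 deletion minus wild type, of the genes on each chromosome. Chromosome I has a median of 0.83 and all others lie between -0.07 and 0.05.

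Genes of the general stress response, which is induced in slow-growing and stressed cells, were lower in the deletion. Of 40 members, 30 fell, 1 rose and 9 were not called, with a median of -0.76 (31 lower and 1 higher when adjusted over the list alone). TKL2 fell by 3.21 and GAC1, a phosphatase subunit of glycogen metabolism, fell by 2.27, while TFS1 rose by 0.47. Camera called the list at adjusted p = 9.4e-08, and gave adjusted p = 0.85 with an estimated correlation. Heat shock proteins and chaperones followed, with 20 of 26 lower, 1 higher and 5 not called, the same numbers when adjusted over the list alone. HSP30 fell by 2.82, the small heat shock protein gene HSP26 fell by 1.76 and the co-chaperone gene SBA1 rose by 0.30. The median was -0.44 (camera adjusted p = 2.3e-05; adjusted p = 0.85 with an estimated correlation).

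Metabolic genes fell in 3 lists. Of 47 genes of amino acid synthesis, 30 fell, 5 rose and 12 were not called, also when adjusted over the list alone, with a median of -0.27. ARG4 of arginine synthesis fell by 1.21 and HOM3 of threonine and methionine synthesis fell by 0.71, while THR1 rose by 0.27 (camera adjusted p = 1.9e-04; adjusted p = 0.85 with an estimated correlation). Among 23 sulfur and methionine genes, 15 fell, 2 rose and 6 were not called, also when adjusted over the list alone. The sulfate permease gene SUL2 fell by 1.03 and SAM3, a transporter of S-adenosylmethionine, fell by 0.99, while MET14 rose by 0.77 and CYS3, which lies on chromosome I, by 0.52. The median was -0.32 (camera adjusted p = 0.028; adjusted p = 0.88 with an estimated correlation). Of 19 genes of the TCA and glyoxylate cycles, 11 fell, 1 rose and 7 were not called, also when adjusted over the list alone. The malate synthase gene MLS1 fell by 2.03 and the malate dehydrogenase gene MDH2 fell by 0.82, with a list median of -0.28 (camera adjusted p = 0.035; adjusted p = 0.88 with an estimated correlation). The sulfur and TCA calls ended without wild type replicate 2 (adjusted p = 0.056 and 0.055) and without npl3 deletion replicate 3 (adjusted p = 0.052 and 0.086).

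Of 13 G2/M genes, 10 rose, none fell and 3 were not called, also when adjusted over the list alone, with a median of 0.34. The kinase gene KIN3, on chromosome I, rose by 1.40 and the mitotic cyclin gene CLB2 by 0.74 (camera adjusted p = 0.010; adjusted p = 0.85 with an estimated correlation). Of 13 daughter-cell and M/G1 genes, 10 fell, 2 rose and 1 was not called, also when adjusted over the list alone, with a median of -0.38. The chitinase gene CTS1 fell by 1.13 and AMN1, an inhibitor of mitotic exit, fell by 1.05, while PRY3 rose by 0.44 and the daughter-specific glucanase gene DSE4 by 0.41 (camera adjusted p = 0.019; adjusted p = 0.85 with an estimated correlation). Genes of ribosome biogenesis moved little: of 79, 37 rose, 3 fell and 39 were not called, with a median of 0.14 (37 higher and 1 lower when adjusted over the list alone). IMP3 and NOP15, both pre-rRNA processing factors, rose by 0.67 and 0.62, and RRB1 fell by 0.20. Camera gave adjusted p = 0.019, and adjusted p = 0.88 with an estimated correlation. The call ended without wild type replicate 3 (adjusted p = 0.060) and without npl3 deletion replicate 3 (adjusted p = 0.072).

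Of 6 a-specific genes, which mark MATa cells, 5 fell and 1 was not called, also when adjusted over the list alone, with a median of -0.47. The a-factor genes MFA1 and MFA2 fell by 0.88 and fell by 0.62. Camera gave adjusted p = 0.041, adjusted p = 0.85 with an estimated correlation and adjusted p = 0.058 without wild type replicate 1. The shortest genes, with a coding length of at most 660 nucleotides, stood higher: 526 of 1096 rose, 194 fell and 376 were not called, with a median of 0.15 (camera adjusted p = 1.3e-04; adjusted p = 0.85 with an estimated correlation). Adjusted over the list alone, 528 were higher and 200 lower.

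**Figure D4:**
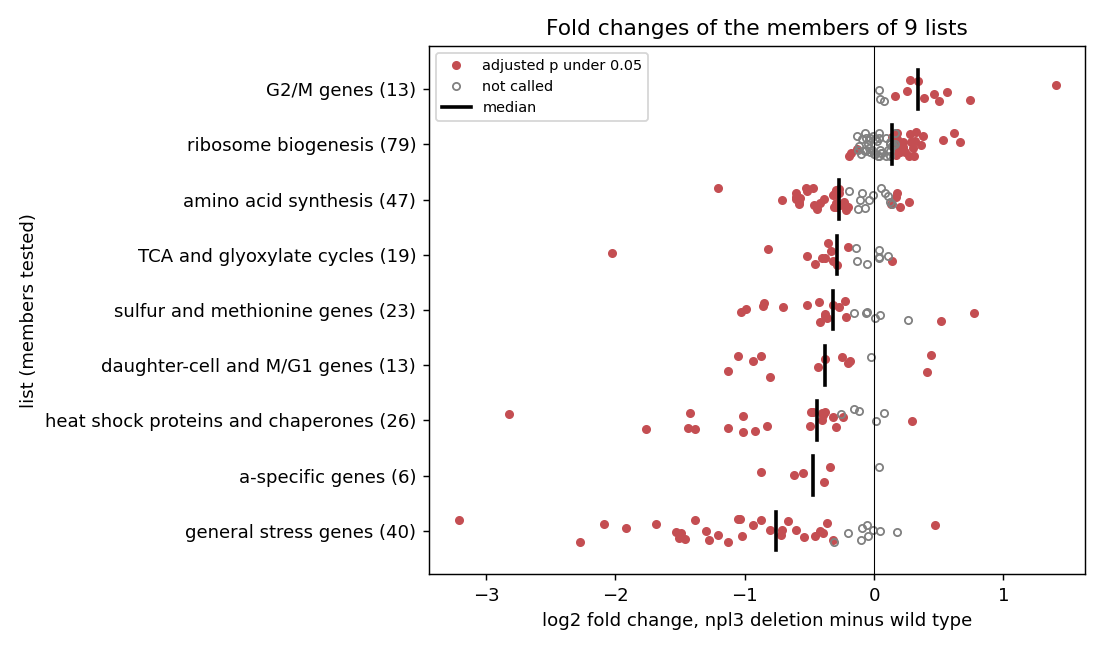
Log2 fold change, npl3 deletion minus wild type, of each member of 9 gene lists called by camera. Filled points passed an adjusted p of 0.05, open points did not, and black lines are medians, from -0.76 for general stress genes to 0.34 for G2/M genes.

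Across the 41 lists, camera called 10, of which 3 were higher and 7 lower. With an estimated correlation it called 0, with 0 at an unadjusted p under 0.05, while fry called 23 and cameraPR 10. Among the 10 called lists the estimated correlation ran from 0.02 (a-specific genes) to 0.54 (heat shock proteins and chaperones). All were above the preset 0.01, so the preset p-values rest on a lower correlation than the one estimated in these data.

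The lists closest to the known roles of NPL3 in splicing, export and genome stability were not called, although single members changed. The values are transcript levels, and spliced and unspliced forms were not told apart. Splicing, export and genome stability themselves were not measured. Outside the ribosomal proteins, the intron list held 51 tested genes named in advance, and it need not hold every gene with an intron. PTC7 and HFM1, among the largest falls, were not on it, and whether they have introns was not looked up. Of 90 ribosomal protein genes with an intron, 13 fell, 2 rose and 75 were not called (median -0.02, camera adjusted p = 0.317). RPL22B fell by 0.76 and RPS22B fell by 0.53, and adjusted over the list alone 2 were lower and 0 higher. Of 38 ribosomal protein genes without an intron, 2 fell, 1 rose and 35 were not called (median 0.03, adjusted p = 0.827), and 0 were called when adjusted over the list alone. Of 57 splicing factors, 26 rose, 9 fell and 22 were not called, also when adjusted over the list alone (median 0.14, adjusted p = 0.071). PRP45, on chromosome I, rose by 0.95 and the core Sm gene SMD1 by 0.87, while LUC7 of the U1 snRNP fell by 1.37 and the helicase gene PRP28 fell by 1.22. This list was called without npl3 deletion replicate 2 (adjusted p = 0.048) and under quantile normalization (adjusted p = 0.044), with adjusted p = 0.85 in the main data with an estimated correlation. Of 28 mRNA export and mRNP genes, 8 fell, 5 rose and 15 were not called (median -0.03, adjusted p = 0.668; 5 lower and 5 higher when adjusted over the list alone). HRB1, an SR-like shuttling protein, fell by 0.53 and the export adaptor gene YRA1 fell by 0.36, while CDC31 and SUS1 rose by 0.54 and 0.42. Among 12 genes of R-loop removal and topoisomerases, 4 rose, 4 fell and 4 were not called, also when adjusted over the list alone (median 0.02, adjusted p = 0.938). TOP3 fell by 1.24 and the helicase gene SEN1 fell by 0.47, while RNH1, a ribonuclease H, rose by 0.42 and TOP1 by 0.39. Of 12 DNA damage-inducible genes, 5 fell, 1 rose and 6 were not called, also when adjusted over the list alone (median -0.03, adjusted p = 0.409). RNR3 and HUG1, both induced by replication stress, fell by 1.22 and fell by 0.98, and the nuclease gene DIN7 rose by 1.24.

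Among 14 hexose transport genes, 7 fell, 3 rose and 4 were not called, also when adjusted over the list alone (median -0.21, mean -0.74, camera adjusted p = 0.066). HXT1, HXT4, HXT7 and HXT3 fell by 4.06, fell by 2.97, fell by 1.44 and fell by 1.14, while HXT2 rose by 0.62. The HXT7 probe set can match several transcripts. The list was called under quantile normalization (adjusted p = 0.044) and without the dimmest genes, where its median was -1.29 (adjusted p = 0.011), with adjusted p = 0.85 in the main data with an estimated correlation. Leaving out dim genes does not alter the fold change of a gene. The median of -1.29 is thus that of fewer members, not of a larger change in the same genes.

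The remaining 24 lists were not called either, with camera adjusted p from 0.116 to 0.938. Numbers of members that rose and fell were 12 and 3 of 18 for meiosis and sporulation, 12 and 4 of 24 for ergosterol synthesis, 1 and 5 of 9 for the zinc regulon, 6 and 10 of 23 for the iron regulon and 7 and 4 of 14 for the phosphate regulon. For glycolysis and fermentation they were 2 and 7 of 21, for the respiratory chain and ATP synthase 15 and 10 of 36, for purine synthesis and one-carbon genes 6 and 8 of 17, for the cell wall 6 and 7 of 22 and for mitochondrial ribosomal proteins 17 and 15 of 68. For transcription elongation and 3′ end formation they were 14 and 6 of 34, for RNA decay 13 and 8 of 37, for translation factors 8 and 1 of 30, for the proteasome 2 and 10 of 35, and for other genes with an intron 16 and 13 of 51. For recombination and checkpoint genes they were 12 and 6 of 32, for DNA replication 17 and 9 of 45, for histones 0 and 4 of 9 and for G1/S genes 6 and 2 of 18. For pheromone response they were 2 and 4 of 11, for alpha-specific genes 1 and 2 of 5 and for haploid-specific genes 5 and 2 of 9. Of the longest genes, 282 of 1092 rose and 332 fell, and of the brightest, 309 of 1090 rose and 258 fell. Adjusted over the list alone, the numbers higher and lower became 12 and 5 for meiosis and sporulation, 8 and 4 for the phosphate regulon, 5 and 0 for translation factors, 2 and 9 for the proteasome, 5 and 3 for haploid-specific genes and 15 and 13 for mitochondrial ribosomal proteins. They became 272 and 327 for the longest genes and 301 and 250 for the brightest, and did not differ for the other lists of these 24.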

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

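The test of the spiked controls was chosen only after their values were seen. Probe sets outside the gene tests also differed between the genotypes. Of 3517 probe sets without a gene, 89 differed, 51 higher and 38 lower in the deletion, at an adjusted p of 0.05, and 417 of the 3517 were above background. Among 47 probe sets for reporter and marker sequences, 4 were higher and 1 lower in the deletion, and the one with the largest rise stood at 1.38 ± 0.23 in wild type and 12.31 ± 0.02 in the deletion (log2, n = 3 arrays each), a measured difference of 10.93 (limma adjusted p = 2.1e-12). The wild type value lies below the background level of 2.13, so the rise is at least 10.2 against that level. Per the labels, the deletion cells carry the KanMX marker in place of NPL3. Whether this probe set reads that marker was not checked. The labelling controls differed by a median of 0.56 and the hybridization controls by a median of -0.82, deletion minus wild type.

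LEU2 rose by 5.66, and by 5.62 to 5.73 with each array left out in turn, although both labels name the same leu2 allele. The strains may therefore differ at LEU2 as well as at NPL3, which was not tested here. Such a difference is not separated from the deletion in any comparison of the groups, amino acid synthesis included.

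The number of genes changed, 3369, was weighed against features of the arrays. A difference in background is left open: the probe sets whose gene is not in the yeast table differed by a median of -0.0107, but normalization holds the dim end of all arrays nearly level (25th percentiles 1.48 to 1.54). Labelling or hybridization that differed between the groups cannot be told apart from the deletion, because the control transcripts moved with the genotype and no array breaks that link: the labelling controls differed by 0.71 in the mean, and by 0.61 without npl3 deletion replicate 1, while the hybridization controls (median -0.82) rest much on that array, with a difference of the means of -0.63 that became -0.29 without it. Such handling could account for part of the changes. Single control probe sets moved by -0.99 to -0.05 (hybridization) and by 0.32 to 1.375 (labelling), deletion minus wild type. Gene changes of that size are not set apart from it. NPL3, at -7.19, changed by more than any spiked control, but its fall was fixed by the deletion. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave 3369 genes, and the highest of the others gave 0; so few splits cannot give a share under 0.05.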

How the results depend on the processing

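Fits without chromosome I genes and without s and x probe sets were chosen after the data were seen. No called result changed sign under any alternative run. Those that did were called in neither fit: BAR1, below background, at -0.18 to 0.07, and 6 lists, R-loop removal, DNA damage, pheromone response, mitochondrial ribosomal proteins and both cytosolic ribosomal protein lists. Of 76 named genes, 67 kept their direction and their side of the threshold throughout; UTP15, KGD2, RPS27A, RPL43B, RPS8B, LYS1 and RPL15A lost and CYM1 gained a call in at least 1 alternative, all with changes of at most 0.20 in size in the main result. Leaving out each array in turn gave 2926 to 3288 changed genes, 917 to 946 changed at least 1.5-fold, 7 to 11 lists and an NPL3 change of -7.39 to -7.08. The count changed at least 1.5-fold, 923, became 370 at a 2-fold threshold and 485 with limma's treat, which are stricter by construction. Without the dimmest genes, where fewer genes were tested, it became 493, while the count of all changed genes went from 3369 to 2577. The 1.5-fold count fell by the larger share, so many of the changes of that size lie in the dimmest genes. With only genes above the background level it was 920. The 10 lists became 0 with an estimated correlation and 23 with fry, which asks a different question and did not call the sulfur list (adjusted p = 0.052). Without the dimmest genes, the a-specific and TCA lists were not called (adjusted p = 0.051 and 0.058) and the iron regulon was (median -0.19, adjusted p = 0.042; 0.202 in the main result and 0.89 there with an estimated correlation). Quantile normalization gave 12 lists. Same-numbered arrays did not deviate together (correlations -0.138, -0.073 and -0.187), so the numbers are not treated as a pairing; with replicate number as a block, 3035 genes were called, 2998 of them shared, with 922 at least 1.5-fold, 10 lists and NPL3 at -7.19. Without chromosome I genes 3287 genes, 854 at least 1.5-fold and 10 lists were called, and without s and x probe sets 3329, 895 and 10. Changes in the 46 genes at or below the background level cannot be measured well.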

Other observations

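The lists on nitrogen, sporulation, flocculins and seripauperins, the look at 15-gene windows, the tests of neighbouring genes and the reading of the mating-type genes against the alpha-specific genes alone were chosen only after results were seen. The lists were drawn up because some of their members had changed, so counts and medians are given for them and no tests.

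Genes under nitrogen catabolite control, which serve the use of poor nitrogen sources, were mostly lower in the deletion. Of 24 members 16 fell, 5 rose and 3 were not called (median -0.69). The general amino acid permease gene GAP1 fell by 2.10, the ammonium permease gene MEP2 fell by 2.07, the proline permease gene PUT4 fell by 2.06 and the allantoate permease gene DAL5 fell by 1.66. RGT1, a repressor of hexose transporter genes, rose by 2.16 (SE 0.08), its partner MTH1 fell by 1.20 (SE 0.10) and RGT2 fell by 0.27, while SNF3 (-0.04, adjusted p = 0.686) and STD1 (-0.13, adjusted p = 0.099) did not pass the test.

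Of 24 middle sporulation and spore wall genes, 14 rose, 3 fell and 7 were not called (median 0.51), while the meiosis and sporulation list fixed beforehand was not called (camera adjusted p = 0.116). GAS2 rose by 3.04, SPO19 by 2.28, SSP2 by 2.01 and SPO73 by 1.23. Of 13 seripauperins, 9 rose and 2 fell (median 0.49), 11 of them on probe sets that can match several transcripts. Of 14 flocculins and adhesins, 7 rose and 3 fell (median 0.18). Among the members that rose, the seripauperin genes PAU7 and PAU8 and the flocculin genes FLO1 and FLO9 lie on chromosome I.

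Chromosome I genes were higher by a median of 0.83 in the deletion. A gain restricted to genes near the ends is argued against, since the 46 genes of its inner part had a median of 0.83. A shift of genes of that brightness through normalization is argued against too: matched genes of other chromosomes had a median of 0.0124 over 1000 draws (95% of draws -0.06 to 0.08, all draws -0.11 to 0.14). A gained copy of the chromosome in the deletion cultures is consistent with the median of 0.83, stated as a hypothesis, although the interval of 0.687 to 0.907 lies below the log2 of a doubling, 1. That interval covers the spread over genes only, and how a doubling would read on these arrays was not tested. DNA was not measured, so a response of these genes to the loss of NPL3 stays open and untested. A gained copy, if present, is not separated from the deletion in any comparison of the groups, genes on other chromosomes included.

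The a-specific genes had a median of -0.47, which raised the question of cells of another mating type or diploid cells. The bound set beforehand to exclude this, all 3 mating-type medians within 0.25 of 0, was not met, because of the a-specific genes themselves. The alpha-specific genes had a median of -0.14, and none reached the 0.5 that the explanation had been stated to need as a median: SAG1 was highest at 0.48, and MF(ALPHA)1, abundant in alpha cells, fell by 0.89. The haploid-specific genes had a median of 0.20, where diploid cells would lower them. These values argue against both kinds of cell as the source, and an effect of the deletion on a-specific genes stays open and untested.

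Outside chromosome I, the 15 genes from HOM3 to THO1 on chromosome V had a median of -0.65, with 11 lower and 1 higher. THO1 fell by 2.09 and PCL6 fell by 1.68. In 1000 shuffles of the gene order, 13 had a window as extreme anywhere (permutation p = 0.014).

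Transcription running on from a same-strand upstream gene was examined as a hypothesis for the genes at least 2-fold higher outside chromosome I. The test could not decide, because its interval runs from a deficit to an excess of 12.2 points. Of these 134, 69 (51.5%) had a same-strand upstream neighbour, against 48.3% of other genes, a difference of 3.20 percentage points (95% interval -5.75 to 12.2). The downstream difference, examined for gene order in general, was 1.02 points. AIM26 lies next to RGT1 on the same strand, and both rose, by 2.32 and 2.16.

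Outside chromosome I, genes at least 2-fold lower had a same-strand downstream neighbour more often than others, 135 of 205 (65.9%) against 46.8%, a difference of 19.1 points (95% interval 12.2 to 26.0, Fisher's exact test, adjusted p = 5.8e-07 over 6 comparisons). Within classes of brightness the odds ratio was 2.01 (1.496 to 2.71). Transcription running on into the next gene could link such pairs, but the downstream neighbours of fallen genes were not higher than those of other genes: the medians differed by -0.0162 (95% interval -0.08 to 0.08, permutation p = 0.576). The reason for the excess was not found.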
